A study of Synechocystis sp. PCC 6803 with 16 samples.

How the data were processed

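The data came from a time course of Synechocystis sp. PCC 6803, a unicellular freshwater cyanobacterium, in 2 strains that both lack slr0242 and differ in what their labels call slr1658m and slr1658c. Per the labels, cells were stripped of iron with EDTA washes, grown without added iron, and returned to iron. RNA was taken at -1 h and at 3, 6 and 24 h relative to the return of iron, in 2 biological replicates, which gave 8 groups and 16 arrays. The labels do not spell out the endings m and c, and the strains are called slr1658m and slr1658c throughout. Per the labels, DNase-treated total RNA was tagged with Cy3 directly, with no cDNA step, so that each probe reads the strand complementary to it. Each array was scanned in 1 colour. All 8 arrays of slr1658m lay on 1 slide and all 8 of slr1658c on another, scanned separately.

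Per the file headers, the scanner files were made with Agilent Feature Extraction 10.7.3.1, with background subtraction, detrending over the slide and surrogate values for spots at background. The deposited processed signal is an intensity per spot that has not been normalised between arrays. The deposited mean, median and local background signals are also intensities per spot. The deposited value table holds log2 intensities. Per the submitters' processing notes limma was used to make it, and neither the version nor the steps are given in the sources used here. All columns of that table have the same distribution, to within 0.0142 on the log2 scale, and a median of 9.55, as quantile normalisation gives. Genome build and probe design are not given in the sources used here.

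Each column of the deposited value table was matched to the scanner arrays by rank. All 16 columns had the same ranks as 1 scanner array (rho = 1, next best at most 0.995), and in all 16 cases that array belonged to another sample. The scanner files were used for all comparisons, with strain and time as their own samples are labelled. The value table was used as an alternative, under its own column labels and with each column matched to the array it equals.

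The array holds 61015 probes besides the scanner's controls, 33 to 60 nucleotides long, with 61007 distinct sequences. Of these, 60866 carry only a serial number, and 149 are named after CRISPR arrays and their leader sequences. The 8 pairs of probes with equal sequence are all named after the first or second CRISPR array (CRISPR1 and CRISPR2). Counts of probes in these groups are therefore not counts of distinct sequences. The files give no gene name or coordinate for any probe, and the reference table supplied could not be matched to the probes. Values are therefore given per probe and not per gene. Lists of iron, photosystem and other genes fixed before the data were examined, values of slr0242, slr1658 and other target genes, and averages over the probes of a gene could not be computed. The rule for naming items, written for protein-coding genes, was applied to probes. It takes those with the largest changes past the threshold whose replicates did not overlap, and for the averaged strain difference those with the same direction at all 4 times. It was used at 24 h, for the averaged strain difference and for the difference between changes at 24 h, and at most 2 probes in each direction are named. The CRISPR and leader groups, and the single members of them that are named, were chosen after their values were seen.

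Processed signals were put on the log2 scale and the 75th percentile over the non-control probes of the array was subtracted. A level of 0 is thus the 75th percentile of the array, and all changes are relative to it. A probe was tested if the scanner software called it well above background on both arrays of at least 1 group, which kept 51848 probes. A kept probe was tested in every comparison, also where it lay at background in both groups and its value was a surrogate. No spot was saturated, and 1 outlier spot was left out. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (prior df 2.68, residual df 8). Each comparison was a contrast of group means, tested two-sided with moderated statistics, and p was adjusted by Benjamini-Hochberg over the 51848 probes of that comparison. The threshold was an adjusted p of 0.05. Differences between the strains' changes were tested as interaction contrasts. Groups of probes were tested with camera at a preset correlation of 0.01, and again with the correlation estimated from the data, adjusted over the groups within a comparison. The group tests take probes as members and the probes of a CRISPR array overlap in what they measure. The estimated correlations were 0.789 for CRISPR1, 0.697 for CRISPR2 and 0.461 for CRISPR3, far above the preset value. Passing at the preset correlation therefore overstates the evidence for these groups.

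Where a probe was not well above background on one side, the fitted change depends on the surrogate value and is not given as a fold. The fold is then a lower bound: the bright group's mean over its replicates against the dim group's mean of, per array, the higher of the array's lowest well-above-background signal and the probe's own. Runs of undetected probes along the numbers in the probe names were set against 100000 random orders (permutation test, one-sided). Pairs of probes that share at least 18 complementary bases were set against 10000 random pairings (permutation test).

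On the arrays, the 75th percentile of the processed signal ran from 857 to 2496, and 61.5% to 80.9% of the probes were well above background. The number of arrays limits the precision, with a median standard error of 0.16 on the log2 scale for a change within a strain, 0.08 for the averaged strain difference and 0.22 for a difference between changes. The fit was tested on simulated data, in which 200 of 51847 probes were given a change. Of 50 probes per size, 7 were recovered at a log2 change of 0.5, 29 at 1, 45 at 2 and 49 at 3, with 8 false calls. With so few changed probes the adjusted threshold is stricter than in the real comparisons, where 28.2% to 89% of probes were called. The recovery rates therefore do not describe the sensitivity there. The correlation of replicate differences across groups gave no pairing of the replicate numbers, and the arrays were treated as unpaired. A term for the slide could not be fitted beside the strain, since each strain has its own slide.

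Alternatives tried were quantile normalisation, normexp background correction with an offset of 50 followed by quantile normalisation, no filter, a filter on every array, variance trend with robust moderation, replicate number as a block, each strain fitted alone, the value table, and leaving out each array in turn.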

Results

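Transcript levels were followed in 2 strains of the cyanobacterium Synechocystis sp. PCC 6803 while iron-starved cultures recovered after iron was given back. Both strains are labelled as lacking slr0242, and they differ in what the labels call slr1658m and slr1658c. The series title places Slr1658 in a regulatory network of this organism. The groups were slr1658m and slr1658c at -1, 3, 6 and 24 h, with 2 biological replicates in each of the 8 groups. The arrays read 61015 probes. The 75th percentile of the signal was 1489 to 2496 in slr1658m and 857 to 1324 in slr1658c, and 37502 to 49382 probes per array were well above background. Replicates correlated across probes at r = 0.985 to 0.993, where probes are not independent of each other.

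Strain and time are named as the scanner files label them. The deposited value table holds the same arrays under other samples' names. Under its own column labels it gives strain differences of the opposite sign, and other time courses, since its columns for 3, 6 and 24 h hold arrays of other times. The data do not settle which labels are right.

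The strain, or the slide and scan that went with it, was the main axis of variation among the 16 arrays. The first principal component held 75.4% of the variance and separated slr1658m from slr1658c at every time. The second held 9.1% and separated the arrays taken before the return of iron from the later ones in both strains. Within slr1658m the distance from the -1 h arrays, as the SD of log2 differences over probes, was 0.66 at 3 h, 0.75 at 6 h and 0.90 at 24 h. In slr1658c it was 0.90, 1.01 and 1.13.

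**Figure D1:**
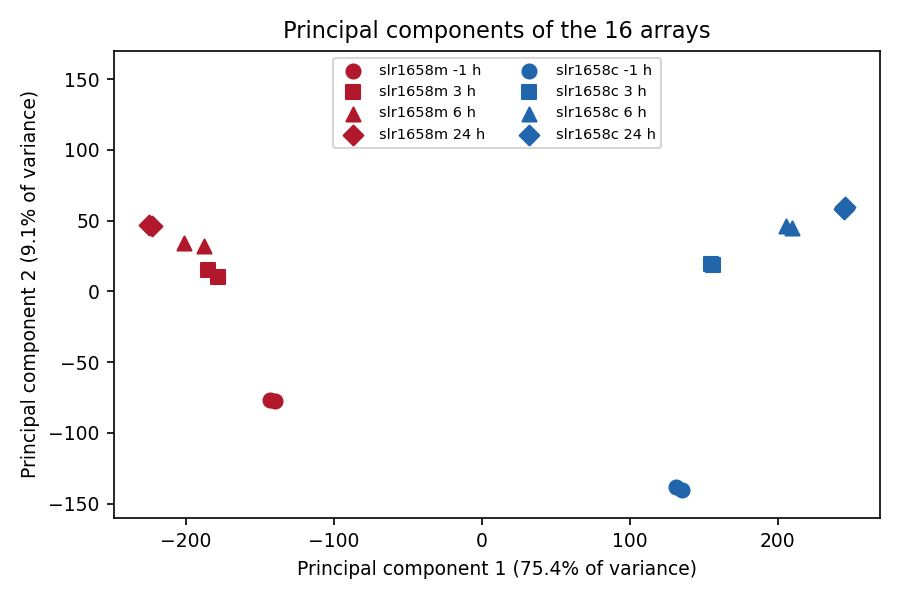
Scores of the 16 arrays on principal components 1 and 2 (75.4% and 9.1% of the variance over 51848 probes, arbitrary units), coloured by strain and shaped by time, with 2 arrays per group. The strains, each on a slide of its own, lie on opposite sides of component 1, and the -1 h arrays of both strains lie lowest on component 2.

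The first question was how transcripts changed in slr1658m as iron returned. Among the largest losses by 24 h were those of a pair of probes with overlapping sequence. SYN-CR-76-11500 (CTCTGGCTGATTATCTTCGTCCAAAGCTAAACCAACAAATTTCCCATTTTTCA) had a log2 level of 1.80 ± 0.08 (SD, n = 2) at -1 h, and was not well above background at 24 h, at least 40.5-fold lower (limma, adjusted p = 2.83e-08). SYN-CR-76-31809 (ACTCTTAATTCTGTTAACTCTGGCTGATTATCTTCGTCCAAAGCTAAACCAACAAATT) went from 1.73 ± 0.09 (SD, n = 2) to not well above background, at least 38.4-fold lower (adjusted p = 3.4e-09). Their intermediate levels were -1.57 ± 0.20 and -1.20 ± 0.16 at 3 h, and -2.34 ± 0.68 and -1.94 ± 0.48 at 6 h. Among the largest gains were those of a pair of probes not well above background at -1 h. SYN-CR-76-46892 (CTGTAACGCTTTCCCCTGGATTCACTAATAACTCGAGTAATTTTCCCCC) reached 1.51 ± 0.14 (SD, n = 2) at 24 h, at least 19.9-fold higher (adjusted p = 5.43e-09), and SYN-CR-76-42273 (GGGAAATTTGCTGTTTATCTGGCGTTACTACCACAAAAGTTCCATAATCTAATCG) reached 0.65 ± 0.08, at least 11-fold higher (adjusted p = 6.51e-07). Their levels at 3 h were 1.73 ± 0.29 and 0.73 ± 0.25. These changes were not particular to slr1658m. In slr1658c SYN-CR-76-11500 and SYN-CR-76-31809 fell from 3.6 ± 0.15 and 3.64 ± 0.24 (SD, n = 2) at -1 h to not well above background at 24 h. SYN-CR-76-46892 and SYN-CR-76-42273 rose there to 0.05 ± 0.04 and 2 ± 0.07 at 24 h.

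Probes against CRISPR arrays, the repeat-spacer loci whose transcripts guide the cleavage of foreign nucleic acids, moved little in slr1658m. At 24 h, 9 of 49 CRISPR1 probes, 10 of 53 CRISPR2 probes and 7 of 36 CRISPR3 probes rose, and 1 of each group fell. The median log2 changes were 0.33, 0.29 and 0.31. Each group passed camera at the preset correlation (adjusted p = 0.0269 for each), and none did with an estimated correlation (adjusted p = 0.824 for each). Without replicate 2 of the -1 h arrays the medians were 0.13, 0.16 and 0.23, and without replicate 2 of the 24 h arrays they were 0.14, 0.17 and 0.14, and in both cases the groups no longer passed. Nor did they under quantile normalisation, with medians of 0.10, 0.25 and 0.25, or with the arrays of slr1658m fitted alone. Under the value table's own labels the medians were -0.64, -0.43 and -0.33. The leader of the second array, the stretch next to a CRISPR array that holds its promoter, was read by 2 tested probes. LEADER2-3 rose by 0.86 ± 0.18 (SE) on the log2 scale at 6 h (adjusted p = 0.00308), and at 24 h its change was 0.12 ± 0.18 (adjusted p = 0.584). LEADER2-2 changed by 0.48 ± 0.15 (SE) at 6 h (adjusted p = 0.0224), which became 0.26 without replicate 1 of the 6 h arrays and then did not pass, nor did it pass without either -1 h array. With the arrays of slr1658m fitted alone, the LEADER2-2 change at 6 h did not pass either (limma, adjusted p = 0.0648). Under the value table's own labels the 6 h changes in slr1658m were 0.17 for LEADER2-3 and 0.24 for LEADER2-2 and did not pass.

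Under the scanner files' labels the number of called probes in slr1658m grew with time. Of 51848 probes tested, 7622 rose and 7015 fell at 3 h, 11869 rose and 8846 fell at 6 h, and 14432 rose and 13536 fell at 24 h (limma, adjusted p threshold 0.05). The called share went from 28.2% through 40% to 53.9%. At 24 h, 5109 probes rose and 4751 fell at least 2-fold. The tests include probes at background in both groups of a comparison, where the surrogate value itself moved. SYN-CR-76-34680, not well above background on any slr1658m array, went from -5.13 ± 0.01 (SD, n = 2) at -1 h to -6.3 ± 0.06 at 6 h. Some of the called falls may therefore be drift of the background level. The balance of directions depended on the filter. Rises made up 52.1%, 57.3% and 51.6% of the calls at 3, 6 and 24 h with the filter used here, 51.2%, 45.8% and 43.7% with no filter, and 44.6%, 46.4% and 45.2% when each probe had to be well above background on every array. With the value table's own labels the calls numbered 27622, 23872 and 26435 at 3, 6 and 24 h, with no growth over time, and rises made up 46.1%, 52.5% and 48.9% of them.

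In slr1658c the second CRISPR array stood out at 24 h. Of 53 CRISPR2 probes tested, 47 rose, none fell, and the median log2 change was 1.65, with the middle 50% of probes between 1.3 and 1.8. The group's median level went from 1.89 ± 0.04 (SD, n = 2) at -1 h through 1.55 ± 0.02 at 3 h and 1.27 ± 0.14 at 6 h to 3.47 ± 0.02 at 24 h. Camera passed at the preset correlation (adjusted p = 1.07e-16) and did not with an estimated correlation (adjusted p = 0.502). Under the value table's own labels the CRISPR2 median was -0.11 and did not pass. The rise followed a loss, since 28 CRISPR2 probes fell at 6 h and none rose. CRISPR1 probes fell at 6 h as well, 33 of 49 with a median of -0.59, and at 24 h their median was -0.22 with 1 probe past the threshold. At 6 h, 15 of 36 CRISPR3 probes fell, and at 24 h 17 rose and none fell, with a median of 0.38. The 6 h losses passed camera at the preset correlation for CRISPR1, CRISPR2 and CRISPR3 (adjusted p = 6.04e-07, 6.28e-06 and 0.000126) and not with an estimated correlation (adjusted p = 0.498 for each). Under the value table's own labels the CRISPR3 median at 6 h was -0.10 and did not pass. For CRISPR3 at 24 h the adjusted p was 0.00162 and 0.749 in the same order, and under quantile normalisation its median of 0.28 did not pass. Under quantile normalisation the CRISPR1 median at 24 h was -0.53, a fall that passed at the preset correlation. It also passed under normexp with quantile normalisation, with a median of -0.52, and with the arrays of slr1658c fitted alone, with -0.22.

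The leader probes of the second array rose in slr1658c at 6 h, when CRISPR2 probes fell, and at 24 h. Both LEADER2 probes rose at 6 h, with a median log2 change of 1.17. At 24 h LEADER2-2 rose by 1.72 ± 0.15 (SE, adjusted p = 2.2e-06) and LEADER2-3 by 1.70 ± 0.18 (SE, adjusted p = 1.11e-05). Under the value table's own labels the 6 h changes were 0.11 for LEADER2-2 and 0.28 for LEADER2-3 and did not pass. None of the 4 LEADER1 probes passed the threshold in slr1658c at 3, 6 or 24 h.

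Unnamed probes changed strongly in slr1658c by 24 h, and those named here moved the same way in slr1658m by less. Between -1 and 24 h in slr1658m, SYN-CR-76-12222 went from -1.29 to 3.08 and SYN-CR-76-30057 from -1.73 to 1.46. SYN-CR-76-1237 went from 3.88 to 0.33 and SYN-CR-76-38240 from 4.43 to -1.59. The values that follow are of slr1658c. SYN-CR-76-12222 (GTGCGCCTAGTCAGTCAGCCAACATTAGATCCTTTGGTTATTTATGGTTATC) was not well above background at -1 h, reached 4.61 ± 0.12 (SD, n = 2) at 3 h and 6.16 ± 0.12 at 24 h, at least 435-fold higher (adjusted p = 4.89e-10). SYN-CR-76-30057 (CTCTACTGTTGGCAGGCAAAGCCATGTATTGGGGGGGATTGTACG) reached 4.82 ± 0.10 (SD, n = 2), at least 172-fold higher (adjusted p = 1.41e-09). SYN-CR-76-1237 (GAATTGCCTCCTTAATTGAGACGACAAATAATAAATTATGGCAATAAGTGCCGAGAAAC) had a level of 5.83 ± 0.06 (SD, n = 2) at -1 h and was not well above background at 24 h, at least 357-fold lower (adjusted p = 1.66e-11). SYN-CR-76-38240 (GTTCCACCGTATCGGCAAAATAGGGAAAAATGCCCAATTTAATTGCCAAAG) was measured on both sides and went from 7.14 ± 0.05 (SD, n = 2) to -2.11 ± 0.47, a log2 change of -9.25 ± 0.22 (SE, adjusted p = 1.92e-10).

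In slr1658c, 13045 probes rose and 10614 fell at 3 h, 13922 rose and 12806 fell at 6 h, and 12235 rose and 15599 fell at 24 h. The called share was 45.6%, 51.6% and 53.7%. At least 2-fold changes at 24 h numbered 5468 up and 6942 down. At 6 h rises made up 52.1% of the calls, against 45.7% with no filter, 48.9% with the filter on every array and 48.9% under quantile normalisation. At 24 h they made up 44%, against 53.7% under the value table's own labels, with 11449 rises and 9878 falls. The calls under those labels numbered 27606, 16527 and 21327 at 3, 6 and 24 h. The time comparisons set arrays of 1 slide against each other, but the -1 and 3 h arrays lay in a different row of the slide from the 6 and 24 h arrays.

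**Figure D2:**
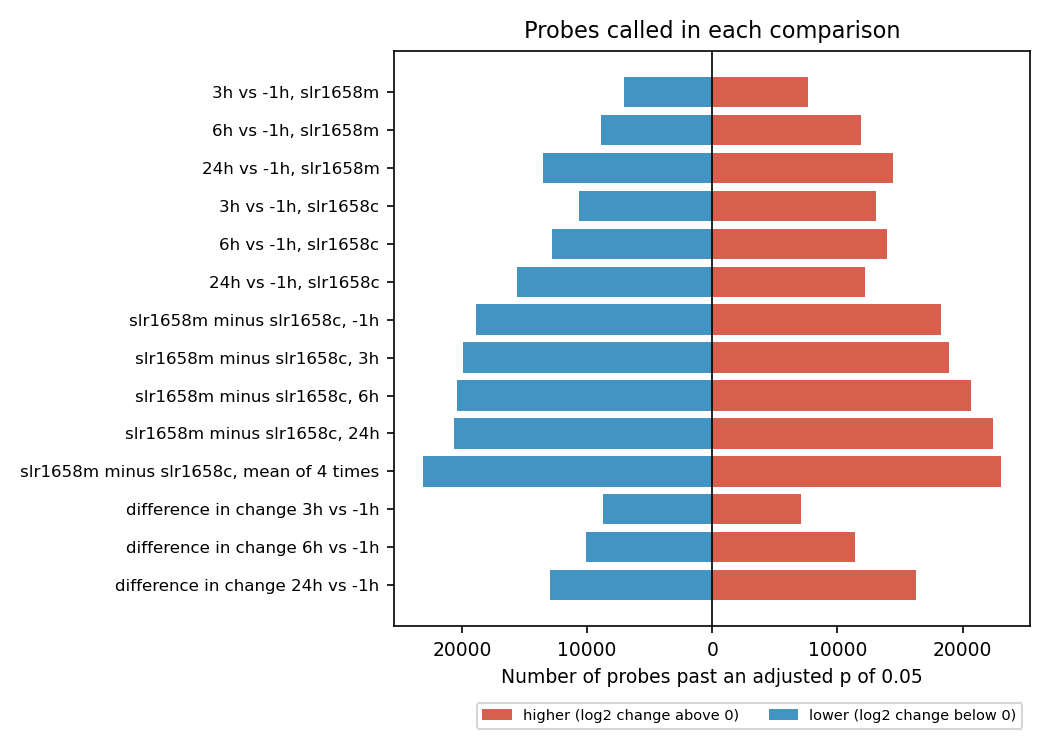
Number of probes past an adjusted p of 0.05 (limma, 51848 probes tested) in each comparison, higher to the right and lower to the left of 0. Under the scanner files' labels, calls in slr1658m went from 14637 at 3 h to 27968 at 24 h (27622 and 26435 under the value table's own labels), and calls between the strains from 37108 at -1 h to 43046 at 24 h.

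The second question was how the strains differed. Most CRISPR2 probes were lower in slr1658m than in slr1658c at every time, 48 of the 48 measured in both strains at -1 h and at 24 h, 47 at 3 h and 46 at 6 h. Averaged over the 4 times, all 48 CRISPR2 probes measured in both strains were lower in slr1658m, with a median log2 difference of -1.85 and a range of -2.81 to -1.27. At -1 h the median over these probes was -1.69 and at 24 h it was -2.98. Of 27 CRISPR3 probes measured in both strains, 26 were lower in slr1658m and 1 was higher, with a median of -1.30. CRISPR1 differed less. Averaged over the times, 37 of 49 CRISPR1 probes were lower in slr1658m and none higher, with a median of -0.35, and at 24 h 6 were lower and the median was -0.14 (camera, adjusted p = 0.251 at the preset correlation and adjusted p = 0.804 with an estimated correlation). Without replicate 2 of slr1658m at 24 h that median was -0.32 and passed at the preset correlation (adjusted p = 0.0294). Over all tested probes of each group, camera at the preset correlation gave adjusted p = 6.26e-08 for CRISPR2, 0.00498 for CRISPR3 and 0.00308 for CRISPR1, and with an estimated correlation adjusted p = 0.554 for each. The CRISPR1 call was also lost under quantile normalisation, with a median of -0.16. The leader probes did not follow their arrays at each time. The 2 LEADER2 probes did not pass at -1 or 3 h, with medians of 0.04 and 0.05. Both were lower in slr1658m at 6 and 24 h, with medians of -0.45 and -1.68. Averaged over the times, 3 of 4 LEADER1 probes were higher in slr1658m and none lower. Their median was 0.38 (camera, adjusted p = 0.216 at the preset correlation).

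Some CRISPR probes gave the opposite picture, with signal in slr1658m and none in slr1658c. Probes CRISPR2-42 to CRISPR2-47 were well above background on 42 of 48 spots in slr1658m and on 0 of 48 in slr1658c. CRISPR2-43 was at least 5.98-fold higher in slr1658m (adjusted p = 8.53e-12). Among CRISPR3 probes, 8 were dark in slr1658c, that is, not well above background on any of its arrays, and seen in slr1658m, and 4 of them, CRISPR3-26 to CRISPR3-29, followed each other in number. CRISPR3-28 was at least 6.91-fold higher in slr1658m (adjusted p = 2.98e-12). CRISPR3-38 was dark in slr1658m and at least 4.52-fold higher in slr1658c (adjusted p = 2.38e-13). No CRISPR1 probe was dark in either strain. A run as long as the 6 in CRISPR2 was very rare in random orders of the probes (permutation test, p = 2e-05, adjusted p = 6e-05 over the groups with dark probes). The run of 4 in CRISPR3 gave p = 0.03 in the same permutation test (adjusted p = 0.045). Random orders take no account of level, which fell with probe number in CRISPR3 on all 16 arrays (rho -0.914 to -0.808 across probes) and in CRISPR2 (rho -0.744 to -0.698). Of other probes as bright in slr1658m, 5 of 8 CRISPR3 probes and 14 of 14 CRISPR2 probes were seen in slr1658c, so that for CRISPR3 the run cannot be set apart from low signal. The files do not say that the numbers follow the order of the spacers.

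**Figure D3:**
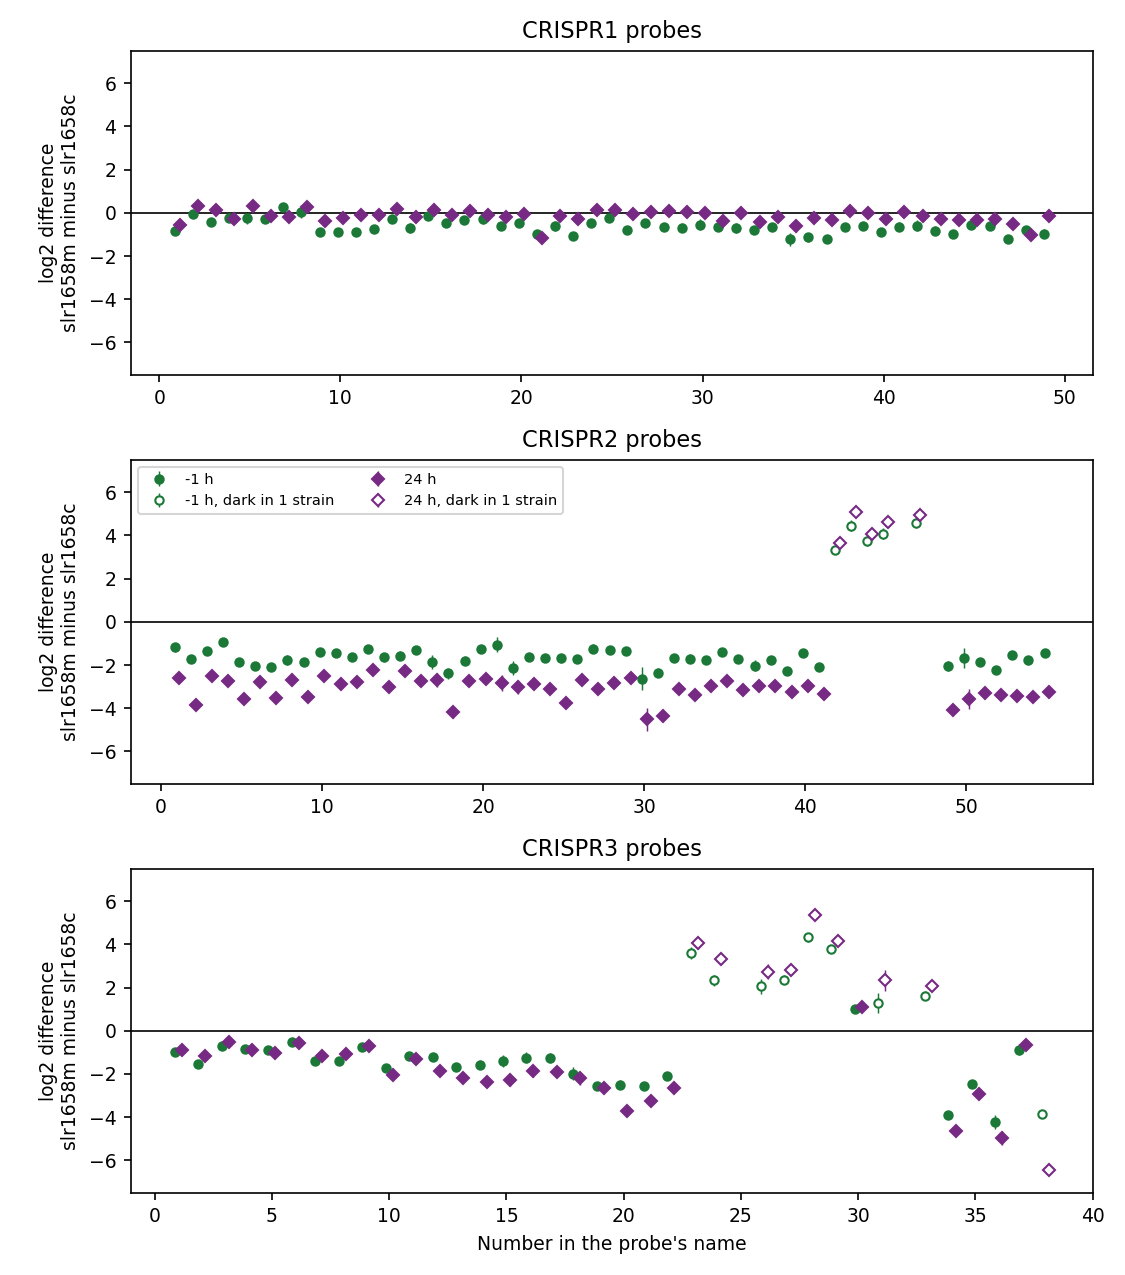
Log2 difference between strains (slr1658m minus slr1658c, with its SE) for each tested CRISPR1, CRISPR2 and CRISPR3 probe, by the number in its name, at -1 h (circles) and 24 h (diamonds). Open symbols mark probes not well above background on any array of 1 strain, whose values are not folds. The 48 CRISPR2 probes measured in both strains lie below 0 at both times, and 5 probes of the run from 42 to 47 lie above 0.

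The largest averaged differences among unnamed probes were also between a clear signal and none. SYN-CR-76-22012 (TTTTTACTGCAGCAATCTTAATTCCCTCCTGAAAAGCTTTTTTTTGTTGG) had levels in slr1658m of 2.37 ± 0.27 (SD, n = 2) at -1 h and 7.18 ± 0.22 at 24 h and was not well above background on any slr1658c array, at least 250-fold higher on average (adjusted p = 2.22e-14). SYN-CR-76-36574 (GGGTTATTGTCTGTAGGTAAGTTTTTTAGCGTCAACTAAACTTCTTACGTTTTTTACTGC) had 2.30 ± 0.25 and 6.74 ± 0.22 in slr1658m and was likewise dark in slr1658c, at least 189-fold higher (adjusted p = 3.11e-14). In the other direction, SYN-CR-76-34680 (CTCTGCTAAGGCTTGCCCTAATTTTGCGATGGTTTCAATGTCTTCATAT) had a level of 1.94 ± 0.17 (SD, n = 8) in slr1658c and none in slr1658m, at least 39.4-fold lower (adjusted p = 2.17e-14). SYN-CR-76-32621 (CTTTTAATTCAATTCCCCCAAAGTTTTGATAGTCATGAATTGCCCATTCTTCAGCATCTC) had 1.77 ± 0.22 (SD, n = 8) in slr1658c and none in slr1658m, at least 35-fold lower (adjusted p = 1.89e-14).

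Between the strains, 18244 probes were higher and 18864 lower in slr1658m at -1 h, and 22421 higher and 20625 lower at 24 h. In total 38853 differed at 3 h and 41013 at 6 h. Averaged over the times, 23047 were higher and 23103 lower, which is 89% of the probes tested. At all 4 times, 13626 probes were higher and 13093 lower. Each strain had its own slide and scan, so that strain and slide cannot be told apart in these differences. When each probe had to be well above background on every array, fewer probes were tested and 26817 differed on average. The share of calls higher in slr1658m at 24 h was 52.1% with the filter used here, 45.6% with no filter and 45.8% with the filter on every array, and at 6 h it was 50.3%, 44.3% and 44.7%. The share was 49.1% at 24 h and 49.7% at 6 h under the value table's own labels.

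The third question was whether the strains responded differently to iron. The CRISPR2 response at 24 h differed, with the change in slr1658m below that in slr1658c for 44 of 53 probes and above it for none, and a median difference between the changes (slr1658m minus slr1658c) of -1.37. Camera gave adjusted p = 2e-10 at the preset correlation and adjusted p = 0.883 with an estimated correlation. Both LEADER2 probes had a lower change in slr1658m, with differences of -1.87 ± 0.21 (SE, adjusted p = 2.45e-05) for LEADER2-2 and -1.58 ± 0.25 (SE, adjusted p = 0.000314) for LEADER2-3. Under the value table's own labels these differences turned to 0.48 and 0.08, and the CRISPR1 median to -0.54. CRISPR1 went the other way, with a higher change in slr1658m for 15 probes, a lower one for 1 and a median of 0.51 (adjusted p = 0.0214, and 0.925 with an estimated correlation). That CRISPR1 call was lost without replicate 2 of slr1658m at -1 h, of slr1658m at 24 h or of slr1658c at 24 h, where the medians were 0.34, 0.31 and 0.49. CRISPR3 had a median of -0.07, with a higher change in slr1658m for 2 probes and a lower one for 6 (adjusted p = 0.359).

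Single probes showed transcripts measured in slr1658m and no longer well above background in slr1658c by 24 h. SYN-CR-76-47965 (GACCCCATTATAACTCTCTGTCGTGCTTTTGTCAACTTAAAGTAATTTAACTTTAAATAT) had levels of 2.26 ± 0.14 and 2.68 ± 0.12 (SD, n = 2) at -1 and 24 h in slr1658m. In slr1658c it had 0.74 ± 0.19 at -1 h and was not well above background at 24 h (adjusted p of the difference between changes = 3.17e-08). SYN-CR-76-9752 (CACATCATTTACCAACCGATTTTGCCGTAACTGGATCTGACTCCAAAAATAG) had 2.59 ± 0.02 and 1.51 ± 0.05 (SD, n = 2) in slr1658m, and went from 2.20 ± 0.11 to not well above background in slr1658c (adjusted p = 1.84e-08). Others appeared in slr1658c alone by 24 h and were dark in slr1658m at both times. SYN-CR-76-57052 (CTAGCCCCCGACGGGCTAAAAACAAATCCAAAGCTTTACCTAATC) reached 2.09 ± 0.06 (SD, n = 2) in slr1658c (adjusted p = 1.27e-07), and SYN-CR-76-47666 (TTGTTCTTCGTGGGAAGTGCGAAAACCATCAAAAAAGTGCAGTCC) reached 1.54 ± 0.06 (adjusted p = 2.59e-08).

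Changes differed between the strains for 15778 probes at 3 h, 21505 at 6 h and 29200 at 24 h. At 24 h the change in slr1658m was the higher for 16264 probes and the lower for 12936, or 55.7% higher, against 49.1% with no filter and 49% with the filter on every array. At 6 h it was the higher for 53% of the calls, against 47.6% with the filter on every array. With the value table's own labels the counts were 27552, 16768 and 21489 at 3, 6 and 24 h, and the change in slr1658m was the higher for 46.9% of the calls at 24 h. Across probes, the changes in the strains correlated at r = 0.48 at 3 h, 0.36 at 6 h and 0.19 at 24 h, with no array shared between them and probes not independent of each other. By rank the correlations were lower, with rho = 0.32, 0.23 and 0.06. At 3 h, 7538 probes were called in the same direction in both strains and 1495 in opposite directions, and at 24 h 9048 and 7524. At 24 h, 4093 probes rose in slr1658m and fell in slr1658c, and 3431 did the reverse. Unrelated calls of the same number would give 4342 and 3194, so the opposite calls were about as many as chance overlap gives. For rises and falls in both strains, 3426 and 5622 were seen against 3406 and 4072. At 3 h the opposite calls numbered 660 and 835, against 1560 and 1765. An effect of the slide that adds equally at all times cancels in these differences, but one that scales with signal does not.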

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

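The tests of explanations below were chosen after the results were seen. The strains' changes since -1 h differed, by the interaction test in limma, for 15778 probes at 3 h, 21505 at 6 h and 29200 at 24 h. At 6 h the CRISPR1 probes had a median difference between changes of 0.42, with 7 of 49 past the threshold, and the CRISPR2 probes one of 0.36, with 3 of 53. Both passed camera at the preset correlation and neither with an estimated correlation (adjusted p = 0.815 for both). At 24 h the CRISPR1 median was 0.51 with 15 probes above 0 and 1 below past the threshold (adjusted p = 0.925 with an estimated correlation). Both LEADER2 probes differed in their change at 24 h, with a median of -1.72.

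The CRISPR2 probes differed in their change at 24 h with a median of -1.37 for slr1658m minus slr1658c, with 44 of 53 past the threshold (adjusted p = 2e-10 at the preset correlation and 0.883 with an estimated correlation). A shift of every probe on the 24 h arrays of slr1658c cannot be tested, since each array's own percentile was subtracted before any comparison. On these arrays the CRISPR1 median change was -0.22 against 1.65 for CRISPR2, so the CRISPR1 probes did not share the rise. Signal close to background is argued against by the 43 CRISPR2 probes well above background on all 16 arrays, whose median was -1.4 with a range of -2.13 to -0.71. Binding through the repeat ends that these probes share, as the whole cause, is argued against by 7 probes with the same ends that were dark in slr1658c at -1, 3 and 6 h, of which 0 were well above background at 24 h, while each of 44 measured probes with these ends gained at least 6.89 times the detection limit. More RNA from the CRISPR2 locus may account for the rise, since the LEADER2 probes, which hold other sequence, rose by a median of 1.71, but they also rose at 6 h when CRISPR2 fell, and whether synthesis or turnover changed was not measured.

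Control spots outside the comparisons also gave signal. By the scanner software, a median of 155.5 of 350 E1A spots per array were well above background (range 17.1% to 59.4%). The median was 45 of 420 ERCC spots (5.7% to 22.6%) and 36 of 156 ETG spots (11.5% to 32.7%). The 308 negative control spots and 35 dark corner spots gave 0% on every array.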

How the results depend on the processing

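Only the value table with matched columns was chosen after seeing the data; the other alternatives were fixed beforehand. All 14 counts of probes stayed within 1.5 times their value under quantile normalisation (ratios 0.935 to 1.05), normexp with quantile normalisation (0.965 to 1.18), no filter (0.933 to 1.3), trend with robust moderation (0.991 to 1.04), replicate blocks (0.919 to 0.999 within strain, 0.977 to 1 across strains), the matched value table (0.944 to 1.13), each strain fitted alone for its own 3 counts (0.932 to 1) and each array left out (0.689 to 1.04). A lone replicate left by such an omission was assumed to vary like the other groups. A filter on every array tested fewer probes, which lowers counts by construction. It gave 13079 and 17374 calls at 6 and 24 h in slr1658m, 16880 and 18084 in slr1658c, 22519, 22861, 24108 and 25107 between strains at -1, 3, 6 and 24 h, 26817 averaged, and 13458 and 17733 differences in change at 6 and 24 h. With an estimated correlation, 18 of 21 group results no longer passed, and the other 3 had not passed before.

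The value table under its own column labels names other arrays, and its results move by that construction. It gave 27622 calls at 3 h in slr1658m, 16527 at 6 h in slr1658c and 27552 differences in change at 3 h. Medians that turned for CRISPR1, CRISPR2 and CRISPR3 were -0.64, -0.43 and -0.33 at 24 h in slr1658m, 0.49, 1.34 and 1.05 between strains at -1 h, and 0.16, 1.44 and 0.91 averaged. For CRISPR2 and CRISPR3 they were -0.11 and -0.06 at 24 h in slr1658c, and 0.96 and 0.57 between strains at 24 h. The CRISPR1 difference in change at 24 h became -0.54. Averaged differences became -8.86 for SYN-CR-76-22012, -7.3 for SYN-CR-76-36574, 5.25 for SYN-CR-76-34680, 4.78 for SYN-CR-76-32621, -2.97 for CRISPR2-43, -2.55 for CRISPR3-28 and 2.64 for CRISPR3-38. Differences in change at 24 h became -2.46 for SYN-CR-76-47965, -2.04 for SYN-CR-76-9752, 2.06 for SYN-CR-76-57052, 2.02 for SYN-CR-76-47666, 0.48 for LEADER2-2 and 0.08 for LEADER2-3. Not run were the median over a gene's probes, the gene lists and target genes (no gene names) and the slide as a block (each strain has its own slide). Signal over background limits what can be read: 12.4% of probes were well above background on no array.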

Other observations

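Of the tests below, the one over other splits of the arrays was chosen beforehand, and those on the dark CRISPR2 run, the value table and the complementary probes were chosen after the results were seen.

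Some probes were well above background in 1 strain alone. Of 61015 probes, 1606 (2.6%) were well above background on all 8 arrays of slr1658m and on none of slr1658c, and 524 (0.9%) showed the reverse. The detection limit differed with the strain, since the lowest well-above-background log2 level per array was -4.02 to -2.80 in slr1658m and -3.60 to -2.47 in the dimmer arrays of slr1658c, so that the imbalance is not a count of transcripts. Another 29934 (49.1%) were well above background on all 16 arrays. Of the probes seen in slr1658m alone, 456 had a partner on the array with complementary sequence. For 202 of them (44.3%) that partner, which reads the other strand, was well above background on all 16 arrays, against 45.5% of the partners of probes seen on all 16 arrays. Of the probes seen in slr1658c alone, 65 had such a partner, and 20 of these partners (30.8%) were well above background on all 16 arrays. The strain difference was alike across times, with correlations across probes of 0.83 to 0.94 between the times, and probes are not independent of each other. Probes of the same strand sharing at least 41 bases (203 pairs) correlated at r = 0.98 in the averaged strain difference.

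Opposite strands of a locus may move in opposite directions between the strains. Of 2569 pairs of complementary probes with both members past the threshold in the averaged strain difference, 1399 (54.5%) had opposite signs. Random pairings gave 47.2% on average, with a range of 43.4% to 50.6% (permutation test, p = 1e-04, the smallest that 10000 shuffles can give, adjusted p = 0.00023 over the comparisons). The excess is small, and the correlation of the difference over the 3216 pairs was -0.19. With changes over time, 54.5% of pairs were opposite at 24 h in slr1658m (adjusted p = 0.00035) and 49% at 24 h in slr1658c (adjusted p = 0.077).

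The run of CRISPR2 probes with signal in slr1658m and none in slr1658c was set against technical explanations. Dimmer arrays of slr1658c are argued against by 14 other CRISPR2 probes as bright in slr1658m, of which 14 were well above background on all arrays of slr1658c, with a median difference of -2.15 (slr1658m minus slr1658c). Random scatter of undetected probes along the numbers is argued against by the adjusted p of 6e-05, which does not allow for the fall of the signal with probe number that the 14 probes of like level address. Spacers that differ or are missing in slr1658c could give the 6 dark probes of the run, and this stays open, since no DNA of the strains was measured and the files do not give the order of the spacers.

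The columns of the value table matched the scanner files of other samples. All 16 columns matched the array found at their place when group names are sorted alphabetically, so a reordering of columns is a candidate explanation. Wrong labels on the scanner files stay open. Under the scanner labels the distance from the -1 h arrays rose with time in both strains (2 of 2), while under the table's labels it was 1.13, 0.90 and 1.01 at 3, 6 and 24 h in slr1658m and 0.90, 0.66 and 0.75 in slr1658c. Among the later times, arrays labelled 3 and 6 h by the scanner files lay closest (0.43 in slr1658m, 0.58 in slr1658c). Those labelled 3 and 24 h lay farthest apart (0.71 and 0.91). Under the table's labels these farthest arrays would be the 3 and 6 h arrays. The distances thus follow the order of time under the scanner labels only. Recovery need not move steadily away from the start, and distances within a strain do not bear on the strain names, so they do not decide which labels are right.

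The averaged strain difference of 46149 probes, on the 51847 probes with a value on every array, was set against other splits of the arrays within each time. Of 100 splits, 1 gave as many, the real one, and the highest other gave 39627. That other split parted the arrays by strain at 3 of the 4 times. Splits that mix the strains add the strain difference to the residual spread, and 76 of the 100 called no probe. The outcome shows that the arrays group by strain or slide, as the first principal component did. It cannot exclude a chance difference between the slides or cultures, and slide and strain cannot be told apart by any split.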
